A study of Mus musculus with 11 samples.

How the data were processed

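Single cells from mouse hippocampus were measured after spared nerve injury (SNI), a model of neuropathic pain in which branches of the sciatic nerve are severed and another is left intact. The tissue was dissociated with type II collagenase, red blood cells were lysed, viability was checked and libraries were made on the 10x Chromium platform, per the labels' protocols. The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, written by Cell Ranger 7.0.1 per the file headers and not normalized by the authors. The genome build was mm10, and R 4.0.0 and Seurat 4.1.0 were also used, per the submitters' processing notes. Whether reads in introns were counted is not given in the sources used here. The matrices hold called cells (smallest total 500 UMIs per barcode), and no annotation of cell types was used here, so cell classes were rebuilt.

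Libraries were grouped by the title label into sham, SNI day 3, SNI day 7, SNI day 14 and SNI day 21, and named by group and replicate number. The titles place the sham libraries on day 7 (replicate 1) and day 3 (replicate 2), but the name of the second one's file says day 7, so whether a day 3 sham exists is uncertain. Nothing in the labels says that libraries came from separate animals, so the p-values measure the spread between these samples, which may be technical. Every pair of libraries differed in counts far beyond sampling noise (lowest chi-square per degree of freedom 39.8), so each counted as 1 replicate.

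Barcodes with at least 300 detected genes and at most 20% mitochondrial UMIs were kept (61997 of 64207). Doublets were predicted in each library from simulated pairs of barcodes, by the share of simulated pairs among nearest neighbours, and the highest scores were removed at an expected rate of 0.8% per 1000 barcodes (3462 barcodes). The remaining 58535 cells were log-normalized and clustered jointly without integration of libraries, on 2000 variable genes (ribosomal and mitochondrial genes left out), 30 principal components, 15 neighbours and the Leiden method at resolution 1 (seed 1), which gave 49 clusters. A cluster was named from marker genes fixed in advance when at least 3 markers were detected in at least 20% of its cells and lay at least 1 log2 unit above the other clusters. A cluster that also held at least 60% of the markers of another, unrelated class stayed unnamed. So did a cluster whose top 10 genes held more markers of another class than of its own. A cluster with few UMIs and none of its class's markers among those genes also stayed unnamed. These naming thresholds were set after the data were seen. The names are reconstructions and stand for cells that carry those markers.

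For each class, UMIs were summed per library (at least 20 cells) and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM normalization, filterByExpr and Benjamini-Hochberg adjustment at 0.05. A single model held the 5 groups. Its contrasts were the mean of the 4 SNI days against sham, each day against sham, and day 21 against day 3. "Called" means an adjusted p below 0.05 over all genes tested. The 4 classes with the most cells in their least filled library were tested in full, and 9 other classes gave counts of calls. Levels are CPM (counts scaled by library total) with the SD over libraries, and log2 fold changes carry their standard error (SE). The test was also run on simulated data, drawn from the means and sizes of the real libraries with 200 genes changed. Every gene was drawn independently with the spread of the trend over genes, so no library differences shared across genes were simulated. Recovery in the real data may be lower. At day 21 against sham it recovered 49% of 2-fold and 87% of 4-fold changes in endothelial cells, 59% and 90% in mature oligodendrocytes, 38% and 80% in microglia, and 53% and 87% in oligodendrocyte precursors.

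Shares of cells (percent of kept cells) were compared between the 9 SNI and 2 sham libraries by a two-sided exact permutation test over 55 splits, which cannot give a p below 0.0364. The smallest groups hold 2 libraries, so shares on single days are given as mean and SD. Trends of a share with day were tested over the 9 SNI libraries by exact permutation of the pairings. Intervals for the share of a single library are exact (Clopper-Pearson) at 95% and cover counting error only. A set of 31 gene lists was tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation, for lists with at least 5 tested members. Their members were also counted as "adjusted over the list alone". The camera p-values were adjusted over the lists within each class and contrast. DESeq2 1.42.0 was the second tool for gene tests.

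The groups, tests, gene lists, cell markers and the rule for named genes were fixed before the data were examined. That rule takes, for the mean of the SNI days, the 10 highest and 10 lowest fold changes among called genes with a mean log2 CPM of at least 5 and at least 8 SNI libraries beyond both sham libraries. For each other contrast it takes the 3 highest and 3 lowest called genes with that mean. Where none passed, it takes the 3 genes with the lowest p, as values. Members of the lists may also be named. Gene models without an assigned name are not spelled out, and results for some genes are not reported here. Reads of genes with near-identical copies, or of genes that overlap another, cannot be assigned with certainty. Alternatives were other size factors, no filter on low counts, DESeq2, the replicate number as a factor, other clusterings, doublets kept, a limit of 10% mitochondrial UMIs, a model with 2 groups, sums thinned to 1 depth, and each library left out in turn. Chosen after seeing the data were offsets that remove a trend with gene length, tests within 1 cluster of a class, the same number of cells drawn from all clusters, a macrophage cluster left out of its class, and the 2 shallowest libraries left out. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 also names. Python 3.11.15 with scipy 1.17.1, leidenalg 0.10.2 and matplotlib 3.10.9 was used.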

Results

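Droplet single-cell RNA sequencing was carried out on hippocampi of 8-week-old C57BL/6 mice at 3, 7, 14 and 21 days after SNI and after sham surgery. The 11 libraries comprised 2 sham libraries, 2 each for SNI days 3, 7 and 14, and 3 for SNI day 21. There was no sham library for day 14 or 21 among those analysed. The total count per library ran from 18170155 to 53775075 UMIs over 2897 to 12801 barcodes. The median UMI count per barcode ran from 3034 in sham replicate 1 to 6327 in sham replicate 2, and SNI day 7 replicate 1 had 3205. The cells fell into 17 named classes of glia, vascular cells, macrophages and neurons. The 4 lead classes, which had the most cells in their least filled library, were endothelial cells (14879 cells), microglia (11064), mature oligodendrocytes (7038) and oligodendrocyte precursors (3112). Choroid plexus epithelial cells (4244) and excitatory neurons (3863) were more numerous than precursors but scarcer in single libraries.

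The first question was whether nerve injury altered the cellular make-up of the hippocampus. Endothelial cells formed 27.1% ± 3.95 (SD, n = 9) of cells under SNI and 22.9% ± 2.41 (n = 2) under sham. Microglia, the resident phagocytes of the brain, formed 14.6% ± 7.88 under SNI and 22.1% ± 14.8 under sham. Mature oligodendrocytes, which make myelin, formed 12.4% ± 3.08 and 13.1% ± 0.529, and oligodendrocyte precursors 6.39% ± 3.2 and 4.83% ± 1.69. Border-associated macrophages were 1.34 percentage points lower under SNI (1.62% ± 0.599 against 2.96% ± 1.14; exact permutation p = 0.0727, adjusted p = 0.927). That class is mixed, since cluster 35, with 368 of its 1211 cells, is led by antigen presentation genes (H2-Eb1, H2-Aa, Cd74) and has none of the class's markers among its top 10 genes. In a division made after the data were seen, the class without cluster 35 formed 1.24% ± 0.413 against 1.82% ± 1.005 (exact p = 0.255), and cluster 35 alone 0.384% ± 0.268 against 1.14% ± 0.134 (exact p = 0.0364, unadjusted). Neuroblasts or immature neurons formed 1.67% ± 0.625 against 3.28% ± 1.88 (exact p = 0.109). None of the 17 classes reached an unadjusted p below 0.05 in this exact test. The edgeR test on cell counts gave unadjusted p of 0.0187 for neuroblasts and 0.0408 for cycling cells, and no class passed adjustment (lowest adjusted p = 0.318). The spread between libraries of 1 group was wide. Microglia made up 32.5% of sham replicate 1 (exact Clopper-Pearson 95% interval 31.4 to 33.6) and 11.6% of sham replicate 2 (10.8 to 12.5). In SNI day 7 replicate 1 they made up 33.0% (32.1 to 33.9). Clusters left without a name held 2.71% ± 0.589 of sham cells, 1.90% ± 0.448 at SNI day 3, 5.66% ± 2.35 at day 7, 6.30% ± 3.31 at day 14 and 6.38% ± 0.723 at day 21 (n = 3). Among them cluster 27, with 8 of 10 microglial markers, held 0.850% ± 0.721 in sham and 0.510% ± 0.0828 at day 3. It held 0.682% ± 0.514 at day 7, 2.60% ± 1.78 at day 14 and 1.37% ± 0.323 at day 21. The microglial shares and tests leave these cells out. Cluster 22, with 9 of 11 astrocyte markers, was likewise left out of astrocytes.

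**Figure D1:**
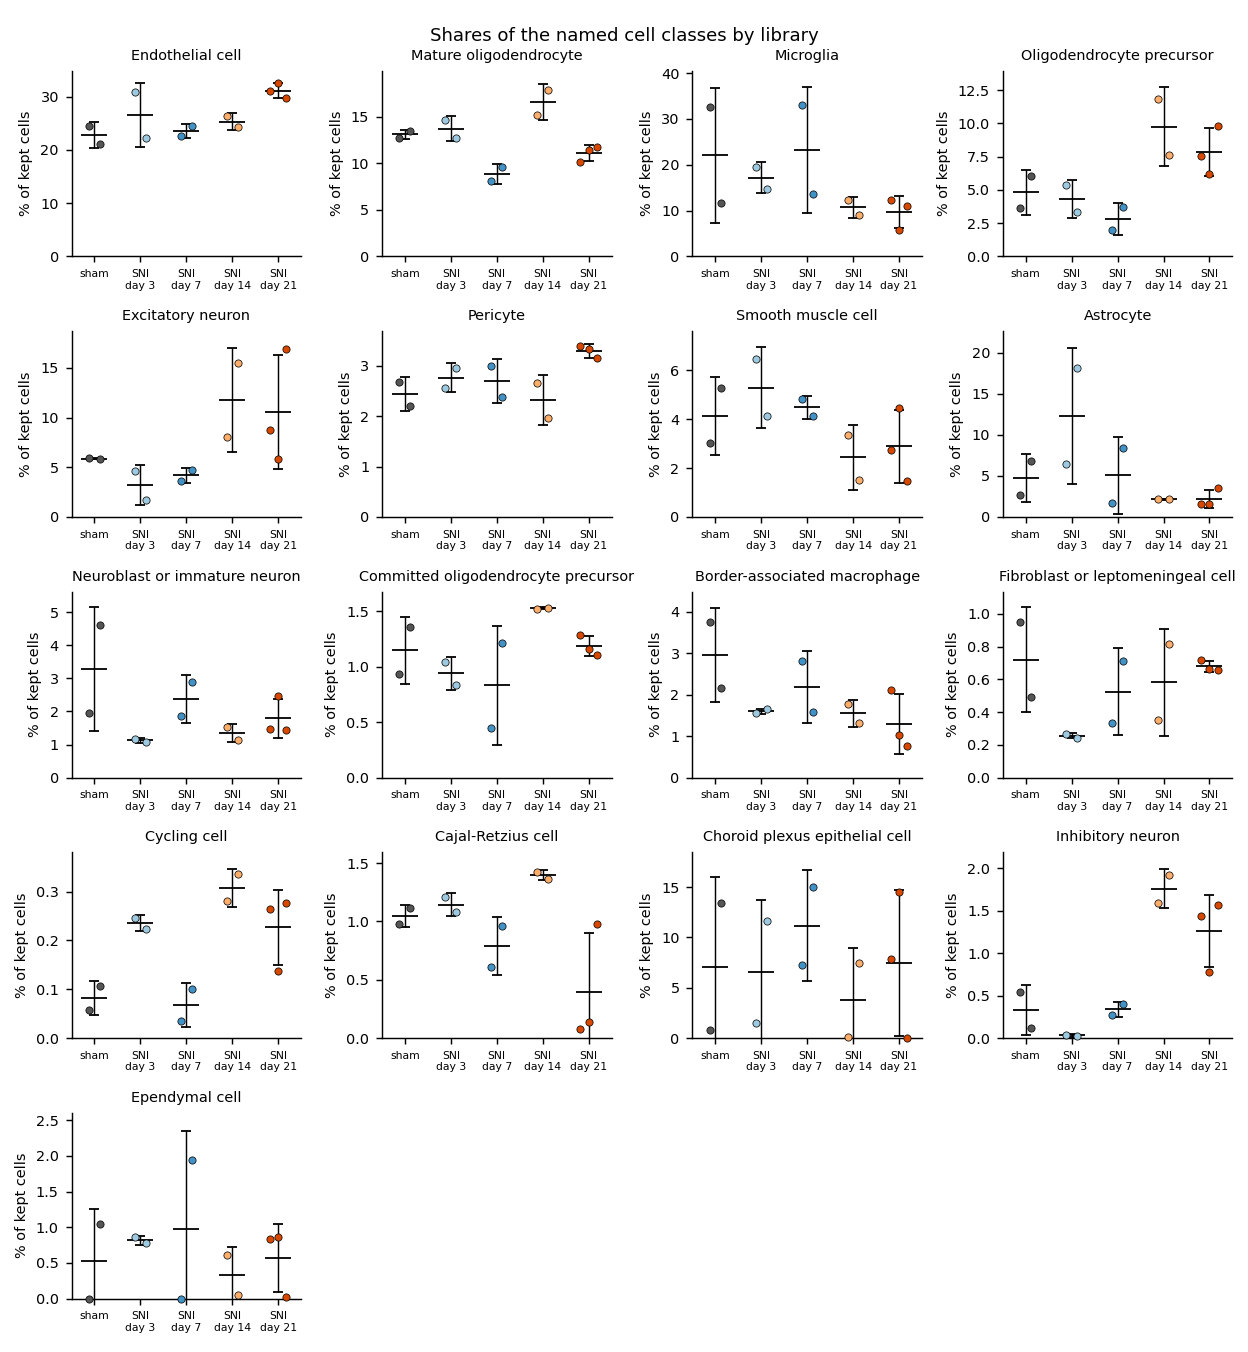
Share of kept cells (percent, y axis) for each of 17 cell classes in sham and at SNI days 3, 7, 14 and 21; dots are libraries, bars the group mean and error bars the SD. Sham microglia sit at 11.6% and 32.5%, and the endothelial share is 31.1% ± 1.39 at day 21 against 22.9% ± 2.41 in sham.

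Over the 9 SNI libraries, excitatory and inhibitory neurons took a larger share of cells on later days and microglia and astrocytes a smaller one. No trend passed adjustment over 17 classes. Excitatory neurons went from 3.17% ± 2.02 (n = 2) at day 3 to 10.5% ± 5.75 (n = 3) at day 21 (r = 0.65, exact p = 0.0575; rho = 0.81, exact p = 0.0122). Inhibitory neurons went from 0.0307% ± 0.0147 to 1.26% ± 0.423 (r = 0.76, exact p = 0.0295; rho = 0.71, exact p = 0.0378). At day 3 the inhibitory neurons were 2 cells and 1 cell. Cajal-Retzius cells, also neurons, went from 1.14% ± 0.0954 to 0.399% ± 0.506 (r = -0.49, exact p = 0.187). In a division made after the data were seen, the rise of excitatory neurons lay in 3 clusters with few UMIs (1.04% ± 0.672 at day 3, 8.03% ± 2.93 at day 21). The other 3 clusters held 2.13% ± 1.345 and 2.503% ± 3.001, with 0.795%, 0.747% and 5.97% in the day 21 libraries. In the same division, the inhibitory cluster with few UMIs went from 0.0102% ± 0.0144 at day 3 to 0.861% ± 0.387 at day 21. The other inhibitory cluster went from 0.0205% ± 0.029 to 0.397% ± 0.0496. Astrocytes went from 12.3% ± 8.27 to 2.23% ± 1.11 (r = -0.66, exact p = 0.0286; rho = -0.70, exact p = 0.0407). Microglia went from 17.2% ± 3.38 to 9.69% ± 3.53 (r = -0.59, exact p = 0.0745; rho = -0.77, exact p = 0.0198). The lowest adjusted p was 0.177 for Pearson's r and 0.169 for Spearman's rho. Without the 2 libraries farthest from the median day, which were both day 3 libraries, r was 0.50 for excitatory neurons (exact p = 0.252), 0.56 for inhibitory neurons (0.191), -0.49 for astrocytes (0.310) and -0.66 for microglia (0.0429). For endothelial cells r went from 0.61 (exact p = 0.0833) to 0.92 (exact p = 0.0143, adjusted p = 0.243).

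Averaged over the 4 SNI days, oligodendrocyte precursors were the only lead class with called genes against sham, and all 4 were lower. Tshz3, which encodes a zinc finger transcription factor (chromosome 7, 36698118 to 36773553), fell by 1.18 ± 0.16 on the log2 scale (edgeR adjusted p = 0.00157). Its level was 200 CPM ± 33.7 in sham, 135 ± 28.2 and 136 ± 35.5 at days 3 and 7, and 59.0 ± 6.75 and 57.6 ± 2.04 at days 14 and 21. It was not called without sham replicate 1 (-0.96, adjusted p = 0.0733) or with 2 groups in the model (-1.16, adjusted p = 0.698). The other called genes encode hemoglobin chains, Hbb-bs (chromosome 7, 103826534 to 103828096; -6.34 ± 0.66, adjusted p = 4.215e-05) and the near-identical copies Hba-a1 and Hba-a2, between which reads cannot be assigned with certainty. In sham, Hbb-bs stood at 438 CPM ± 604, so that a single sham library carried it. It was not called without sham replicate 2 (-1.105, adjusted p = 0.686) or with 2 groups in the model (-5.51, adjusted p = 0.0577). Between 88.6% and 83.1% of precursors at days 14 and 21 lay in cluster 10, and cluster 19 held 78.6% of precursors in sham replicate 1 and 52.2% in sham replicate 2. Leaving out sham replicate 2 gave 232 called genes, SNI day 7 replicate 1 gave 24 and SNI day 7 replicate 2 gave 7.

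In the other lead classes edgeR called 0 genes for the mean of the SNI days. The genes with the lowest p in endothelial cells included Flrt2 (-0.64 ± 0.11), a cell adhesion gene (adjusted p = 0.393). In mature oligodendrocytes they were Ssc4d (-2.82 ± 0.45), Arhgef40 (-1.52 ± 0.25; both adjusted p = 0.105) and Tulp3 (-0.85 ± 0.17; adjusted p = 0.508). In microglia they included Chst8 (1.06 ± 0.17; adjusted p = 0.201) and Plk3 (1.26 ± 0.21; adjusted p = 0.21). Immediate early genes, which cells switch on within minutes of a stimulus, had 0 of 22 members called in microglia and 0 of 21 in mature oligodendrocytes, and 19 and 12 higher when adjusted over the list alone (camera adjusted p = 0.407 and 0.138 with an estimated correlation). Unadjusted p fell below 0.05 for 877 endothelial, 584 oligodendrocyte and 1666 microglial genes, and DESeq2 called 7, 3 and 114. Without sham replicate 2, edgeR called 55, 430 and 599 genes. Other single libraries gave at most 2, namely 1 in endothelial cells (SNI day 7 replicate 1) and, in mature oligodendrocytes, 2 (SNI day 3 replicate 2, sham replicate 1) or 1 (SNI day 14 replicate 2, SNI day 21 replicate 1).

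At day 3 few genes were called against sham. In mature oligodendrocytes Rras, a small GTPase gene (chromosome 7, 45017961 to 45021647), fell by 1.35 ± 0.19 on the log2 scale (edgeR adjusted p = 0.031; 33.4 CPM ± 4.21 in sham, 13.4 ± 0.933 at day 3). Fmn1, a formin that nucleates actin filaments, rose by 1.38 ± 0.21 (adjusted p = 0.0425; 21.5 CPM ± 4.90 to 58.0 ± 7.81). The neuronal transcript Bc1 stood at -1.50 ± 0.25 there (adjusted p = 0.0727) and at -2.08 ± 0.34 in oligodendrocyte precursors (adjusted p = 0.0516). In microglia Ier2, an immediate early gene (chromosome 8, 84661331 to 84662852), fell by 1.67 ± 0.20 (adjusted p = 0.0259), from 498 CPM ± 36.8 to 159 ± 20.8. Members of the oxidative phosphorylation list in mature oligodendrocytes had a median of -0.70, with 0 of 30 called and 27 lower when adjusted over the list alone (camera adjusted p = 0.502 with an estimated correlation). Cluster 11 held 55% of microglia at day 3. The sham libraries differed: cluster 1 held 75.0% of microglia in replicate 1 and 31.1% in replicate 2, and cluster 11 held 4.70% and 25.7%.

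At day 3 edgeR called 2 genes in mature oligodendrocytes, 1 in microglia and 0 in endothelial cells and precursors, where unadjusted p fell below 0.05 for 2198, 1212, 1143 and 502 genes. DESeq2 called 382, 19, 5 and 2. Leaving out sham replicate 2 raised the edgeR counts to 2080, 420, 131 and 68. The precursor count was 5 without sham replicate 1 or either day 7 library, 4 without either day 14 library, 2 without SNI day 3 replicate 2 and 1 without SNI day 21 replicate 2 or 3. The oligodendrocyte count was 0 without SNI day 3 replicate 3 or SNI day 21 replicate 1 and 1 without sham replicate 1. The Ier2 call in microglia was lost (0 genes) without SNI day 3 replicate 3, either day 14 library, SNI day 21 replicate 3 or sham replicate 1. At day 7 edgeR and DESeq2 called 0 genes in all 4 lead classes. Unadjusted p fell below 0.05 for 202 endothelial, 382 oligodendrocyte, 86 microglial and 343 precursor genes. The lowest p values belonged to Sugct (-0.76 ± 0.20) and Fez1 (-0.65 ± 0.18) in endothelial cells, Rdh12 (-1.18 ± 0.27) and the histone copy Hist2h2aa1 (1.46 ± 0.30) in mature oligodendrocytes, Dennd5b (-1.75 ± 0.42), Morrbid (-1.13 ± 0.29) and Scnn1a (-2.63 ± 0.69) in microglia (adjusted p of at least 0.9998 each), and the hemoglobin genes in precursors (Hbb-bs -5.42 ± 1.14, adjusted p = 0.454). The day 7 count was 1 in endothelial cells without sham replicate 2, and 4 and 3 in precursors without sham replicates 1 and 2.

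In endothelial cells, which line the brain's vessels, the genes called at days 14 and 21 included linker histone and AP-1 genes. The linker histone gene Hist1h1e (chromosome 13, 23620629 to 23622558) rose by 2.43 ± 0.30 at day 14 and 2.04 ± 0.28 at day 21 on the log2 scale (edgeR adjusted p = 0.0101 and 0.016), from 21.6 CPM ± 3.91 in sham to 118 ± 21.5 and 88.5 ± 23.4. Reads of this family of near-identical histone genes are uncertain in their assignment. Jund (chromosome 8, 70698949 to 70700616), an AP-1 transcription factor, rose by 1.93 ± 0.31 and 1.91 ± 0.30 (adjusted p = 0.0248 and 0.0236), and the linker histone gene H1f0 rose by 2.09 ± 0.37 at day 14 (adjusted p = 0.0337). The ribosomal protein gene Rps21 (-1.65 ± 0.26; adjusted p = 0.0219) and Rundc3b (-1.45 ± 0.24; 0.0252) fell at day 14. Clu, an extracellular chaperone (-1.35 ± 0.23; 0.0378), and Tshz3 (-1.13 ± 0.18; 0.0359) fell at day 21. Without sham replicate 1 none of Hist1h1e (1.90), Jund (1.53), Clu (-1.37) and Tshz3 (-1.17) was called at day 21 (adjusted p = 0.123 each), and H1f0 was not at day 14 (1.78; adjusted p = 0.0684).

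Of 22 immediate early genes tested in endothelial cells, 3 rose at day 14 and 2 at day 21 (12 and 17 higher when adjusted over the list alone; medians 1.41 and 1.65; camera adjusted p = 0.581 and 0.374 with an estimated correlation). The interferon list had 0 of 23 called at day 21 and 17 higher when adjusted over the list alone (median 1.17; camera adjusted p = 0.507 with an estimated correlation). Its mean of log2(CPM + 1) was 8.22, 7.36 and 6.11 in day 21 replicates 1, 2 and 3, and 6.31 and 6.08 in sham. In all, 64 genes were called at day 14 (41 higher, 23 lower) and 23 at day 21 (15 higher, 8 lower), and DESeq2 called 283 and 299. Clusters 2 and 3 held 17.4% and 51.2% of the class in sham replicate 1 and 41.4% and 10.7% in sham replicate 2. Clusters 8 and 9 held most of the late cells (33.8% and 22.2% at day 14, 29.0% and 29.8% at day 21). Within cluster 2 alone 16 and 94 genes were called, against 30 and 10 in as many cells drawn from all clusters. The day 14 count was 175 without SNI day 7 replicate 1, 169 without SNI day 7 replicate 2, 145 and 112 without sham replicates 1 and 2, 5 and 1 without SNI day 14 replicates 1 and 2, and 24 and 31 without SNI day 21 replicates 1 and 2. The day 21 count was 562 without sham replicate 2, 1 without sham replicate 1, 54 and 51 without SNI day 7 replicates 1 and 2, and 3, 4 and 61 without SNI day 21 replicates 1, 2 and 3.

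Mature oligodendrocytes at days 14 and 21 were marked by a rise of immediate early genes. Ier2 rose by 2.46 ± 0.34 at day 14 and 2.37 ± 0.33 at day 21 (edgeR adjusted p = 0.00661 and 0.0107), and Dusp1, a phosphatase that ends MAP kinase signalling, by 2.39 ± 0.34 and 2.40 ± 0.32 (0.00661 and 0.0107). Btg2, an antiproliferative gene, rose by 2.31 ± 0.39 at day 14 (0.0212), and the AP-1 gene Junb (chromosome 8, 84974484 to 84978718) by 2.54 ± 0.29 at day 21 (0.00256). Junb stood at 121 CPM ± 38.5 in sham, 54.6 ± 24.6 at day 3, 195 ± 58.1 at day 7, 516 ± 67.6 at day 14 and 712 ± 92.8 at day 21. Plat, which encodes tissue plasminogen activator (-1.56 ± 0.24; 0.0128), and Itih3 (-1.20 ± 0.22; 0.0318) fell at day 14, and Tcf20, a transcriptional coregulator (-0.96 ± 0.17; 0.0418), fell at day 21.

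Of 21 immediate early genes in mature oligodendrocytes, 9 rose at day 14 and 8 at day 21, and 19 at each day when adjusted over the list alone (medians 1.68 and 1.76). Over all lists, lead classes and contrasts, these were the only camera calls that held with an estimated correlation (adjusted p = 0.0496 and 0.0401). That adjustment ran over the lists within each class and contrast, not over all 708 list tests. Both days were set against the same sham libraries, so these calls are not independent of each other. EdgeR called 48 genes at day 14 (35 higher) and 17 at day 21 (13 higher), and DESeq2 called 225 and 133. Cluster 0 held between 80.0% and 88.9% of the class in every group, and within it 49 and 27 genes were called. The day 14 count was 0 without either SNI day 14 library, 551 and 125 without sham replicates 1 and 2, 108 and 99 without SNI day 7 replicates 1 and 2, 30 without either day 3 library and 27 without SNI day 21 replicate 1. The day 21 count was 629 without sham replicate 2, and 4 and 1 without SNI day 21 replicates 2 and 3.

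**Figure D2:**
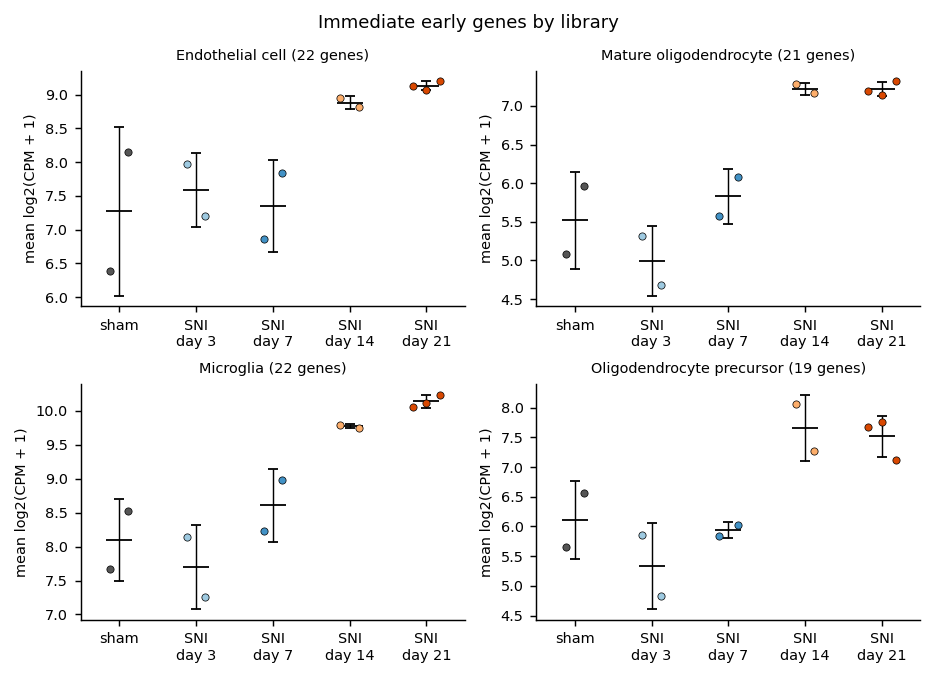
Mean of log2(CPM + 1) over the tested immediate early genes (y axis) in sham and at SNI days 3, 7, 14 and 21, with 1 panel for each lead cell class; dots are libraries, lines the group mean and error bars the SD. In microglia the mean is 8.10 ± 0.60 in sham and 10.14 ± 0.09 at day 21, and in mature oligodendrocytes 5.52 ± 0.62 and 7.22 ± 0.09.

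In microglia at days 14 and 21 the called genes included members of the cytokine, interferon and antigen presentation lists. Tnf (chromosome 17, 35199381 to 35202007), a cytokine, rose by 3.36 ± 0.94 at day 21 (edgeR adjusted p = 0.0409), from 253 CPM ± 280 in sham to 2512 ± 696. Dusp2, a MAP kinase phosphatase, rose by 3.71 ± 1.053 (0.043). Tas1r1, a taste receptor subunit gene (chromosome 4, 152027914 to 152038568), rose by 4.19 ± 0.81 at day 14 and 3.52 ± 0.77 at day 21 (0.0141 and 0.0173), from 8.01 CPM ± 3.63 to 150 ± 46.8 and 93.9 ± 7.42. Ifi27l2a, an interferon-stimulated gene, and Marcksl1, a cytoskeletal regulator, rose at day 14 by 3.81 ± 0.95 and 3.64 ± 0.90 (0.0353 and 0.0345). The histone gene Hist1h1d, with near-identical relatives, fell by 2.59 ± 0.64 and 2.27 ± 0.55 (0.0334 and 0.0238). All of these calls were lost without sham replicate 1. There, Tnf stood at 2.52, Dusp2 at 2.76, Marcksl1 at 2.86, Ifi27l2a at 4.37, Tas1r1 at 4.81 and 4.15, and Hist1h1d at -1.21 and -0.88 (adjusted p from 0.0640 to 0.349). Tnf and Dusp2 are also among the 10 leading genes of cluster 6, which held most late microglia. The sham replicates 1 and 2 held Dusp2 at 6.23 and 97.7 CPM and Hist1h1d at 152 and 37.1 CPM.

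Of 23 interferon genes in microglia, 2 rose at day 14 and 14 at day 21 (5 and 21 when adjusted over the list alone; medians 1.32 and 2.32; camera adjusted p = 0.623 and 0.401 with an estimated correlation). Isg15 rose by 3.02 ± 0.62 at day 21, from 12.6 CPM ± 5.64 to 97.1 ± 55.5. SNI day 21 replicate 3 stood apart on this list, with means of log2(CPM + 1) of 5.92, 5.05 and 3.13 in day 21 replicates 1, 2 and 3, and 2.96 and 2.97 in sham. Of 23 inflammatory and NF-kB target genes, 5 rose at day 14 and 8 at day 21 (12 at each when adjusted over the list alone; medians 1.90 and 2.00; camera adjusted p = 0.429 and 0.401 with an estimated correlation). They included the NF-kB inhibitor genes Nfkbia (2.98 ± 0.69) and Tnfaip3 (2.06 ± 0.47) at day 21, and Il1b, Ccl3 and Ccl4 were not called (2.00, 1.78 and 1.35; adjusted p = 0.277, 0.185 and 0.277). Of 16 antigen presentation genes, 5 and 7 rose (8 at each when adjusted over the list alone; camera adjusted p = 0.429 and 0.401 with an estimated correlation), among them the class I genes H2-K1 (2.00 ± 0.32 and 1.92 ± 0.30) and H2-D1 (1.69 ± 0.32 and 1.80 ± 0.31), which share sequence with each other. Immediate early genes rose for 18 and 20 of 22 members (20 and 21 when adjusted over the list alone; medians 1.75 and 1.99; camera adjusted p = 0.429 and 0.144 with an estimated correlation). Of 15 glucocorticoid response genes 7 rose at day 21 (8 when adjusted over the list alone; camera adjusted p = 0.144 with an estimated correlation), among them Tsc22d3 (1.32 ± 0.27), Per1 (1.67 ± 0.35) and Sgk1 (0.91 ± 0.24).

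Among 17 genes of homeostatic microglia, 2 fell and 1 rose at each late day. The fractalkine receptor gene Cx3cr1 fell by 0.55 at day 14 and by 0.47 ± 0.14 at day 21 (edgeR adjusted p = 0.0491 and 0.0471), Sall1, a transcription factor of microglial identity, fell by 0.95 ± 0.18 at day 21, and Jun rose by 1.73 ± 0.18. P2ry12 (0.24) and Tmem119 (0.13) were not called at day 21. Of 14 myelin genes, 2 fell in microglia at day 21 (median -1.21; camera adjusted p = 0.543 with an estimated correlation). EdgeR called 1012 genes at day 14 (580 higher) and 1388 at day 21 (808 higher). Cluster 1 held 75.0% of microglia in sham replicate 1 and 31.1% in sham replicate 2, and cluster 6 held 0.0871% and 25.1% there and 86.5% and 87.9% at days 14 and 21. Within cluster 16, the cluster with the most cells in its least filled library, 29 and 8 genes were called, against 146 and 225 in as many cells drawn from all clusters. The day 14 count was 637 and 633 without SNI day 3 replicates 2 and 3, 95 and 19 without SNI day 14 replicates 1 and 2, 670 without SNI day 21 replicate 2 and 60 without sham replicate 1. The day 21 count was 479, 702 and 748 without SNI day 21 replicates 1, 2 and 3 and 266 without sham replicate 1.

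Genes were also called at the late days in oligodendrocyte precursors, the dividing cells that give rise to oligodendrocytes. Socs3, a feedback inhibitor of cytokine signalling (chromosome 11, 117966079 to 117970047), rose by 3.07 ± 0.68 at day 14 and 2.58 ± 0.66 at day 21 (edgeR adjusted p = 0.00389 and 0.00998), from 26.9 CPM ± 14.1 to 261 ± 238 and 202 ± 131. Traf5, a signalling adaptor, rose by 2.41 ± 0.47 and the pseudogene Nutf2-ps1 by 2.49 ± 0.49 at day 14 (0.00192 and 0.00194), and Fos, an AP-1 gene, and Ccn1, a matricellular protein gene, rose by 2.00 ± 0.50 and 1.87 ± 0.40 at day 21 (0.00906 and 0.00447). Without sham replicate 1 Fos was not called (1.36; adjusted p = 0.0873), and Ccn1 stood at 1.38 there and at 3.80 without sham replicate 2. The lowest fold changes belonged to Hbb-bs (-4.15 ± 0.86 and -8.87 ± 1.19; 0.00263 and 0.000869), Hba-a1 (-4.14 ± 0.81 and -8.52 ± 1.18) and the microglial complement gene C1qa (-3.62 ± 1.047 and -4.03 ± 1.00; 0.0158 and 0.00843). These rested on 1 sham library each: without sham replicate 2 Hbb-bs stood at 1.04 at day 14, and Hba-a1 was listed at 0 in the other sham library, and without sham replicate 1 C1qa stood at 0.67 and 0.27. Likewise 10 of 16 genes of homeostatic microglia fell in precursors at each day (13 and 14 lower when adjusted over the list alone; medians -2.49 and -2.61; camera adjusted p = 0.792 and 0.536 with an estimated correlation).

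Nuclear-encoded oxidative phosphorylation genes rose in oligodendrocyte precursors for 28 of 30 members at day 14 and 11 at day 21 (29 and 18 when adjusted over the list alone; medians 0.94 and 0.47; camera adjusted p = 0.513 and 0.484 with an estimated correlation). Cox7c, a subunit of cytochrome oxidase, went from 346 CPM ± 23 in sham to 795 ± 82.1 at day 14 and 571 ± 18 at day 21. With offsets that removed the trend with gene length, 6 and 0 of the 30 were called higher (medians 0.30 and -0.01). Of 13 genes encoded in mitochondrial DNA, 8 fell at day 21 (9 when adjusted over the list alone; median -0.99; camera adjusted p = 0.484 with an estimated correlation). Ribosomal protein genes rose for 47 of 80 and fell for 1 at day 14 (52 and 2 when adjusted over the list alone), and rose for 13 at day 21 (2 when adjusted over the list alone; camera adjusted p = 0.792 and 0.536 with an estimated correlation). With those offsets 2 rose and 9 fell at day 14, and 0 rose and 7 fell at day 21. The rise of both lists is thus not separable from gene length, with which the fold change correlated at a Spearman value of -0.59 and -0.60 across genes, which are not independent. Of 20 cholesterol synthesis genes, 2 rose at day 14 and 10 at day 21 (11 when adjusted over the list alone; median 0.87; camera adjusted p = 0.484 with an estimated correlation), among them Idi1 (1.31 ± 0.26) and Insig1 (1.06 ± 0.23, edgeR adjusted p = 0.00507). With the offsets 0 and 1 of the 20 were called.

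Of 20 synapse genes in precursors, 7 fell and 1 rose at day 21 (9 and 1 when adjusted over the list alone, median -0.43, camera adjusted p = 0.484 with an estimated correlation), among them the adhesion gene Nlgn1 (-1.047 ± 0.19). No count with length offsets is given for this list. The fold change correlated with gene length at -0.60 across genes, so the part of gene length in this fall stays open. Immediate early genes rose for 12 of 19 at day 14 and 13 at day 21 (6 and 5 with length offsets; 15 and 13 when adjusted over the list alone; medians 1.57 and 1.17; camera adjusted p = 0.513 and 0.484 with an estimated correlation). Pdgfra, the receptor that marks the class, was not called at day 21 (-0.07). EdgeR called 3222 genes at day 14 (1880 higher) and 3197 at day 21 (1532 higher), and 926 and 510 with offsets that removed a trend with gene length. Cluster 19 held 78.6% and 52.2% of precursors in sham replicates 1 and 2, and cluster 10 held 88.6% and 83.1% of those at days 14 and 21. Within cluster 10 alone 20 and 7 genes were called, against 1957 and 1369 in as many cells drawn from all clusters. The day 14 count was 774 without SNI day 14 replicate 1 and 1739 without sham replicate 1. The day 21 count was 1895 and 1993 without SNI day 21 replicates 2 and 3 and 990 without sham replicate 1.

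**Figure D3:**
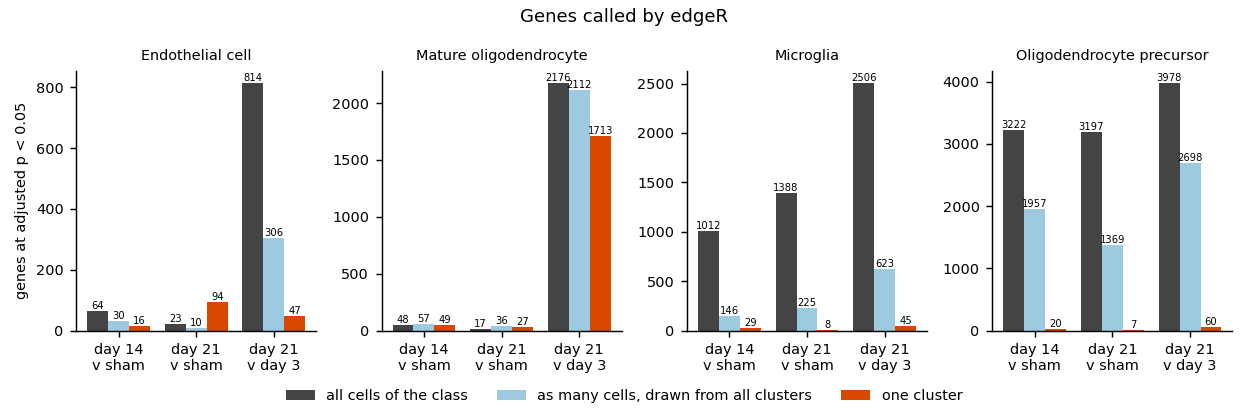
Number of genes called by edgeR (y axis) in each lead class for day 14 and day 21 against sham and day 21 against day 3, with bars for all cells, for as many cells drawn from all clusters and for cells of 1 cluster. In oligodendrocyte precursors at day 21 against day 3 the bars stand at 3978, 2698 and 60.

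The comparison of SNI day 21 with SNI day 3 asked how expression differed between the latest and the earliest time. In mature oligodendrocytes, immediate early genes rose for 19 of 21 members (21 when adjusted over the list alone; median 2.41; camera adjusted p = 0.0643 with an estimated correlation), led by Junb (3.71 ± 0.31; edgeR adjusted p = 3.954e-05), Ier2 (3.33 ± 0.35; 0.00031) and Btg2 (3.19 ± 0.40; 0.000531). Cholesterol synthesis genes rose for 11 of 20 (15 when adjusted over the list alone; median 0.59; camera adjusted p = 0.349 with an estimated correlation), among them Msmo1 (0.97 ± 0.20). Myelin genes rose for 6 of 17 (7 when adjusted over the list alone; median 0.27; camera adjusted p = 0.349 with an estimated correlation). Mog, a surface protein of myelin, rose by 0.74 ± 0.15, from 2076 CPM ± 104 at day 3 to 3449 ± 31.9 at day 21 with 2652 ± 126 in sham, and Mbp was not called (0.06). Lysosomal genes rose for 7 of 25, among them Ctsl (1.37 ± 0.20), and glucocorticoid response genes for 7 of 16, among them Ddit4 (1.47 ± 0.25) (8 and 7 when adjusted over the list alone, with 1 lysosomal gene lower; camera adjusted p = 0.428 and 0.492 with an estimated correlation).

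Genes that fell in mature oligodendrocytes between days 3 and 21 were led by the cadherin gene Cdh20 (chromosome 1, 104768529 to 104995481; -1.62 ± 0.19; edgeR adjusted p = 0.000365), Lrmda (-1.61 ± 0.24; 0.00135) and the noncoding host gene Mir100hg (-1.56 ± 0.19; 0.000531). Astrocyte homeostasis genes fell for 5 of 14 and rose for 1 (6 and 1 when adjusted over the list alone; camera adjusted p = 0.349 with an estimated correlation), among them the glutamate transporter gene Slc1a2 (-1.35 ± 0.28), while the astrocyte share of the libraries went from 12.3% to 2.23%. In all, 2176 genes were called (989 higher, 1187 lower), with a median genomic length of 10650 bp for the higher and 111448 bp for the lower genes. With offsets that removed the trend with gene length 818 were called (519 higher). Within cluster 0 alone 1713 genes were called. The count was 884 and 120 without SNI day 3 replicates 2 and 3, and 1254, 1061 and 1420 without SNI day 21 replicates 1, 2 and 3.

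In microglia the same comparison gave higher immediate early, interferon and inflammatory genes. Ier2 rose by 3.71 ± 0.21 (edgeR adjusted p = 2.658e-06), from 159 CPM ± 20.8 to 1999 ± 298. Ppp1r15a, a stress-induced phosphatase subunit, rose by 3.54 ± 0.68 (0.00475) and Tas1r1 by 3.57 ± 0.77 (0.00811). Immediate early genes rose for 20 of 22, interferon genes for 16 of 23, inflammatory genes for 10 of 23 and antigen presentation genes for 9 of 16 (21, 23, 14 and 13 when adjusted over the list alone; medians 2.43, 2.69, 1.95 and 0.85). With an estimated correlation the camera adjusted p = 0.192, 0.55, 0.565 and 0.311. SNI day 21 replicate 3 did not share the interferon rise: the mean of log2(CPM + 1) over that list was 5.92, 5.05 and 3.13 in day 21 replicates 1, 2 and 3, and 3.05 and 2.74 at day 3. Adamts16, a metalloproteinase gene, fell by 1.93 ± 0.20 (0.000365), and Apoe, a lipid carrier raised in disease-associated microglia, fell by 0.54 ± 0.18 (0.0498). In all, 2506 genes were called (1161 higher, 1345 lower), the higher with a median length of 13378 bp and the lower of 85863 bp, and 1433 (809 higher) with offsets that removed the trend with gene length. Cluster 11 held 55% of microglia at day 3 and cluster 6 held 87.9% at day 21. Within cluster 16 alone 45 genes were called, against 623 in as many cells drawn from all clusters. The count was 1358 and 252 without SNI day 3 replicates 2 and 3, and 1628 without SNI day 21 replicate 1.

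In endothelial cells between days 3 and 21, Ifi27l2a rose by 2.85 ± 0.75, the interferon regulator Irf7 by 2.40 ± 0.57 and Dusp1 by 2.36 ± 0.57 (edgeR adjusted p = 0.0445, 0.0337 and 0.0344). The rise of Ifi27l2a was absent from SNI day 21 replicate 3, with 210, 176 and 20.5 CPM in the day 21 libraries and 19.3 and 19.5 in those of day 3. Vegfc, a lymphangiogenic growth factor, fell by 1.79 ± 0.30 (0.0144), from 80.4 CPM ± 23.1 to 22.4 ± 2.18. It is among the 10 leading genes of cluster 12, which held 13.3% and 16.5% of the class in the day 3 libraries and 4.88%, 4.59% and 3.72% in those of day 21. Irf7 likewise leads cluster 8, and stress genes (Hspa1a, Hspa1b, Hspb1) and Cxcl1 lead cluster 9. Immediate early genes rose for 9 of 22, interferon genes for 6 of 23 and antigen presentation genes for 4 of 16 (18, 22 and 9 when adjusted over the list alone; medians 1.70, 1.26 and 0.90; camera adjusted p = 0.570, 0.570 and 0.698 with an estimated correlation). Irf7 stood at 514 CPM ± 385 at day 21. Over the interferon list the mean of log2(CPM + 1) was 8.22, 7.36 and 6.11 in day 21 replicates 1, 2 and 3, and 6.14 and 6.02 at day 3. Of 21 blood-brain barrier genes, Cav1 fell by 0.64 ± 0.15 and no other was called. In all, 814 genes were called (339 higher, 475 lower; median lengths 8940 and 137525 bp), and 118 (69 higher) with offsets that removed the trend with gene length. Cluster 2 held 44.2% of the class at day 3, and clusters 8 and 9 held 29.0% and 29.8% at day 21. Within cluster 2 alone 47 genes were called, against 306 in as many cells from all clusters. The count was 3 and 301 without SNI day 3 replicates 3 and 2, 452 and 427 without SNI day 14 replicates 1 and 2, 97, 18 and 309 without SNI day 21 replicates 1, 2 and 3, and 1411 and 1392 without sham replicates 1 and 2.

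In oligodendrocyte precursors between days 3 and 21, Socs3 rose by 3.21 ± 0.68 and Ier2 by 2.92 ± 0.30 (edgeR adjusted p = 0.00233 and 6.647e-05). Pola1, a DNA polymerase subunit gene (chromosome X, 93304767 to 93632155), fell by 1.67 ± 0.22 (0.000464), the centrosomal gene Cep128 by 1.64 ± 0.28 (0.000917) and mt-Co3, a mitochondrially encoded cytochrome oxidase subunit (chromosome M, 8607 to 9390), by 1.66 ± 0.32 (0.00123). Oxidative phosphorylation genes rose for 28 of 30, immediate early genes for 17 of 19, ribosomal protein genes for 49 of 80 (1 fell) and interferon genes for 8 of 13 (28, 17, 53 and 8 when adjusted over the list alone; camera adjusted p = 0.363, 0.363, 0.492 and 0.532 with an estimated correlation). With length offsets 1, 11, 1 and 1 of these rose. The mean of log2(CPM + 1) over the interferon list was 5.43, 4.32 and 3.13 in day 21 replicates 1, 2 and 3, and 2.89 and 2.53 at day 3. Synapse genes fell for 6 of 20 (6 when adjusted over the list alone), among them Nlgn1 (-1.15 ± 0.19) and Grin1 (-0.86 ± 0.22). For synapse genes no count with length offsets is given, and the fold change correlated with gene length at -0.63 across genes. In all, 3978 genes were called (1985 higher, 1993 lower; median lengths 8923 and 123971 bp), and 970 with offsets that removed the trend with gene length. Cluster 19 held 59.7% of precursors at day 3 and cluster 10 held 83.1% at day 21. Within cluster 10 alone 60 genes were called, against 2698 in as many cells from all clusters. Without SNI day 3 replicate 3 the count was 743.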

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

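The tests chosen after the result was seen are the offsets that remove a trend with gene length and their bound, the comparison of hemoglobin levels between classes, the tests within single clusters of each class, and the spread applied to nuclear transcripts.

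Expression differed between day 21 and day 3 for 814 genes in endothelial cells, 2176 in mature oligodendrocytes, 2506 in microglia and 3978 in precursors. The edgeR test compared these days directly, so the level in sham does not enter the contrast. The sham libraries still enter the normalization, the filter and the estimate of the spread. Leaving out single libraries moved these counts between 3 (without SNI day 3 replicate 3) and 1411 (without sham replicate 1) in endothelial cells, and down to 120, 252 and 743 in the other classes, each without SNI day 3 replicate 3. When the 5 libraries of days 14 and 21 were set against the 4 of days 3 and 7, edgeR called 2183, 1576, 3754 and 5494 genes in the same order of classes. Of 100 splits drawn from the 126 possible, only the real one, 1 split in each class, gave as many genes. The highest of the other splits gave 1, 10, 563 and 2201. This grouping of days was not among the contrasts fixed beforehand, and nothing in the labels says that libraries came from separate animals. The splits thus describe these libraries and do not exclude a chance division.

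Immediate early genes had medians above 0 at day 21 against day 3 in all 4 lead classes. These were 1.70, 2.41, 2.43 and 2.20 on the log2 scale in endothelial cells, mature oligodendrocytes, microglia and precursors. In that order 9 of 22, 19 of 21, 20 of 22 and 17 of 19 members were called higher. With an estimated correlation the list passed camera in none of these classes. A difference in depth stays open: the lowest median was 1.689 with all sums thinned to 1 depth, but thinning keeps each gene's expected share and leaves depth per cell unmatched. A shift between clusters stays open by the test set beforehand on the lowest median within single clusters, 0.8762 in microglia on as few as 21 cells per library. By tests per class added afterwards, the median in mature oligodendrocytes was 2.395 within cluster 0 and 2.41 in all cells. Cluster 0 held between 80.0% and 88.9% of that class in every group, so the rise did not need a shift between these clusters. A shift between states inside cluster 0 was not tested and stays open. In endothelial cells (1.236 and 1.70) and precursors (1.366 and 2.20) the median was lower within 1 cluster but stayed above 0. There a shift stays open as part of the cause. Handling of the tissue on the late days stays open: the median was above 0 in 12 of the 13 classes tested, choroid plexus epithelium (-0.35) being the exception, and time after injury predicts the same. These cannot be told apart because no sham library of day 14 or 21 was analysed.

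Genes that fell from day 3 to day 21 were long and genes that rose were short, with Spearman correlations across genes, which are not independent replicates, between length and fold change of -0.42, -0.47, -0.32 and -0.63 in the 4 lead classes. Whether a length bias between libraries made this trend stays open, since the offsets remove it by construction. With offsets 13.02%, 29.2%, 48.1% and 17.9% of the calls were also called, above a bound set after the result was seen. This argues only against a bias set by gene length alone as the whole cause of the calls. The offsets remove the mean trend, so a bias that differs between genes of the same length stays open. Less nuclear or unspliced RNA on the late day predicts a fall of transcripts kept in the nucleus in all 4 classes, and their medians were 0.244 ± 0.427 (SE), -0.159 ± 0.437, 0.514 ± 0.609 and -0.723 ± 0.292. Medians above 0 in 2 classes had been set beforehand as arguing against it, and only the condition on spread, added after these values were seen, leaves it open. The transcripts included Meg3, also a member of the list of neuronal transcripts, at 1.708, 1.645, 2.345 and 0.105 in the 4 classes. These medians therefore do not measure nuclear RNA alone.

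The fall of hemoglobin transcripts in oligodendrocyte precursors rested on sham replicate 2, where 3 cells held 99.89% of hemoglobin UMIs and a single cell held 2628 of 2633. Hemoglobin stood at 1345 CPM in those precursors and 3.224 CPM in mature oligodendrocytes of that library, a ratio of 417.2. That single cell sets the ratio, which is therefore no separate test. Free RNA from red blood cells is argued against as the source of this level, because a single cell held nearly all of it. Droplets that also held a red blood cell are therefore a candidate explanation, although red blood cells were lysed during preparation. Without sham replicate 2, Hbb-bs in Oligodendrocyte precursor, SNI day 14 against sham, stood at 1.037.

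Astrocytes made up 18.1% of SNI day 3 replicate 3 (exact Clopper-Pearson 95% interval 17.0 to 19.2), apart from the other SNI libraries, of which the nearest had 8.40%. Ependymal cells made up 1.942% of SNI day 7 replicate 2 (1.61 to 2.32), where the nearest SNI library had 0.863%. Their gaps were 0.586 and 0.556 of the range. Both are above the Dixon limit for 9 libraries, which chance passes in about 1 of 20 groups, so that chance gives about 1 such class among the 17 screened. Cluster 30 held 4.933% of SNI day 7 replicate 1 (558 cells) and carried genes of cerebellar granule cells, with Gabra6 at 740 CPM against 0.0258 in the sham libraries, Cbln3 at 512, Grm4 at 468, Cbln1 at 411 and Fat2 at 351.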

How the results depend on the processing

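The tests chosen after seeing the data are those with gene length offsets, within 1 cluster, on as many cells drawn from all clusters, with the 2 shallowest libraries left out (sham replicate 1 and SNI day 7 replicate 1), with sham and SNI day 7 alone, with cluster 35 left out of border-associated macrophages, and day 21 against day 3 with thinned sums. No share of a cell class passed adjustment in any setting tried, and other size factors kept every count of called genes within 1.5 times. Other Leiden resolutions and the limit of 10% mitochondrial UMIs did so for the mean of the SNI days, the only contrast they were run for. Of 75 calls of named genes, 21 were kept in every setting. Most calls were lost without SNI day 14 replicate 2 (28), SNI day 14 replicate 1 (27) or sham replicate 1 (24), and 20 were lost with length offsets and 4 of 71 with DESeq2. With 2 libraries in most groups, leaving out 1 leaves a lone library that is assumed to vary like the other groups. In the following, counts of called genes are in the order endothelial cells, mature oligodendrocytes, microglia and oligodendrocyte precursors, only counts moved by over 1.5 times are given, and the cause was not tested unless stated.

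Without a filter on low counts, the mean of the SNI days gave 300, 146, 795 and 220 genes, day 3 gave 266, 514, 325 and 76, and day 7 gave 34, 50, 22 and 11. Day 14 gave 801, 452 and 1924 in the leading 3 classes, day 21 gave 1013, 416 and 2224, and day 21 against day 3 gave 1624 in endothelial cells. DESeq2 gave 7, 3, 114 and 125 for the mean of the SNI days, 5, 382, 19 and 2 at day 3, 283 and 225 at day 14 and 299 and 133 at day 21 in endothelial cells and oligodendrocytes. Length offsets gave 5 genes at day 21 and 118 between days 21 and 3 in endothelial cells, 0 at day 3 and 818 between days in oligodendrocytes, 0 at day 3 and 1433 between days in microglia, and 926, 510 and 970 at day 14, at day 21 and between days in precursors. Thinned sums gave 1, 1 and 40 for the mean of the SNI days in oligodendrocytes, microglia and precursors, and 2432 between days in precursors. For precursors, that mean gave 2 with doublets kept and 2 with 2 groups in the model. Of the 2 named genes called there, Tshz3 and Hbb-bs, the model with 2 groups lost both and the doublets kept lost Hbb-bs.

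Without the 2 shallowest libraries, which leaves 1 sham library, endothelial cells gave 1 gene at day 7, 624 at day 14 and 2047 between days 21 and 3. Oligodendrocytes gave 4 for the mean, 9, 10, 1263 and 243 at days 3, 7, 14 and 21, and 3627 between days. Microglia gave 2 for the mean, 2 at day 3 and 742 at day 21, and precursors gave 9 for the mean, 8, 3 and 1887 at days 3, 7 and 21. Within 1 cluster against as many cells from all clusters, endothelial cells gave 16 against 30 at day 14, 94 against 10 at day 21 and 47 against 306 between days. Oligodendrocytes gave 27 against 36 at day 21. Microglia gave 29 against 146, 8 against 225 and 45 against 623, and precursors 20 against 1957, 7 against 1369 and 60 against 2698. Of 708 list tests camera called 241, of which the estimated correlation left 2; fry called 49, and without sham replicates 1 and 2 camera called 241 and 326.

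Replicate numbers were not taken to pair the libraries, since no label says so. Of 17 same-numbered pairs per class, 6, 3, 4 and 4 had correlated deviations over 0.1 (range -0.17 to 0.32, -0.21 to 0.24, -0.08 to 0.55 and -0.21 to 0.30). In groups of 2 libraries the deviations from the group mean mirror each other. Many of these pairs therefore repeat 1 value, and the tally cannot decide whether the numbers pair the libraries. The highest value in each class, 0.319, 0.236, 0.553 and 0.299, is that of sham with SNI day 7. With the replicate number as a block, endothelial cells gave 1 gene for the mean, 81 at day 21 and 518 between days 21 and 3, oligodendrocytes gave 1 at day 3, and precursors gave 12 for the mean and 1 at day 3. Sham and day 7 alone with the block gave 19, 1 and 26 in endothelial cells, oligodendrocytes and microglia. The block changed no other count by over 1.5 times.

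Leaving out each library in turn, the mean of the SNI days ranged over 0 to 55, 0 to 430, 0 to 599 and 4 to 232, each highest without sham replicate 2. Day 3 ranged over 0 to 131, 0 to 2080, 0 to 420 and 0 to 68, highest without sham replicate 2, and day 7 over 0 to 1 in endothelial cells and 0 to 4 in precursors. Day 14 ranged over 1 to 175, 0 to 551, 19 to 1435 and 774 to 3482. Day 21 ranged over 1 to 562, 1 to 629, 266 to 1785 and 990 to 3589. Day 21 against day 3 ranged over 3 to 1411, 120 to 3158, 252 to 2879 and 743 to 4245, each lowest without SNI day 3 replicate 3. Signs turned in precursors only, for genes that rested on counts in 1 sham library. Hbb-bs in Oligodendrocyte precursor, SNI day 14 against sham, ran from -12.32 without SNI day 14 replicate 1 to 1.037 without sham replicate 2. Hba-a1 in Oligodendrocyte precursor, SNI day 14 against sham, ran from -10.82 to 6.646 without the same libraries. These Hba-a1 folds, the -12.32 of Hbb-bs and the 2.403 below are fitted against a library at 0 CPM, so that the prior count sets their size. Hba-a1 in Oligodendrocyte precursor, SNI day 21 against sham, ran from -9.3 without sham replicate 1 to 2.403 without sham replicate 2. C1qa in Oligodendrocyte precursor, SNI day 14 against sham, ran from -4.982 without SNI day 14 replicate 1 to 0.672 without sham replicate 1, and was 0.6381 without the 2 shallowest libraries. C1qa in Oligodendrocyte precursor, SNI day 21 against sham, ran from -5.25 without sham replicate 2 to 0.2657 without sham replicate 1, and was 0.3395 without the 2 shallowest libraries.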

Other observations

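The tests described here were chosen after the results were seen, except the counts for gene lists, the counts in other classes and the shares at Leiden resolution 2. In microglia between days 3 and 21, endoplasmic reticulum stress genes rose for 6 of 13 tested members (6 when adjusted over the list alone; median 0.54; camera adjusted p = 0.435 with an estimated correlation) and oxidative stress genes for 8 of 18 (11 when adjusted over the list alone; median 0.81; camera adjusted p = 0.311 with an estimated correlation). At day 21 against sham, 5 of 18 oxidative stress genes rose, among them Hmox1, which degrades heme (1.71 ± 0.38), Slc7a11, the cystine importer (2.09 ± 0.50), and Ftl1, a ferritin chain (0.97 ± 0.17). The complement receptor genes C3ar1 (1.00 ± 0.21) and C5ar1 (1.71 ± 0.49) rose. In oligodendrocyte precursors glycolysis and hypoxia genes rose for 9 of 19 at day 14 (9 when adjusted over the list alone, camera adjusted p = 0.513 with an estimated correlation), with Ldha at 1.495 ± 0.26 and Bnip3 at 1.42 ± 0.28. No count with length offsets is given for this list, and the fold change correlated with gene length at -0.59 across genes in these precursors. At day 21 interferon genes rose there for 6 of 13 (7 when adjusted over the list alone; median 1.29; camera adjusted p = 0.536 with an estimated correlation), with Ifit3 at 3.06 ± 0.66, though the mean of log2(CPM + 1) over this list was 3.13 in SNI day 21 replicate 3 against 5.43 and 4.32 in replicates 1 and 2. Most cells of these classes lay in other clusters on the late days than in sham, cluster 6 for microglia and cluster 10 for precursors.

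Outside the lead classes, edgeR called 10 genes in neuroblasts or immature neurons for the mean of the SNI days, all lower, 24 at day 21 (6 higher) and 149 between days 21 and 3 (21 higher), and DESeq2 called 3, 49 and 173. Between those days edgeR called 29 genes in border-associated macrophages (9 higher), a mixed class, 14 in smooth muscle cells (9 higher) and 11 in committed oligodendrocyte precursors (6 higher). Excitatory neurons had 0 called by edgeR (1893 at an unadjusted p below 0.05), where DESeq2 called 385. Immediate early genes rose for 7 of 19 members in neuroblasts (median 1.62), 7 of 21 in smooth muscle cells (1.20), 3 of 17 in committed oligodendrocyte precursors (2.40) and 0 of 20 in excitatory neurons (0.17). These classes were not refitted without single libraries.

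An unnamed cluster with pericyte and endothelial markers (cluster 24) held 0.378% ± 0.214 of sham cells, 0.153% ± 0.0156 at day 3, 0.650% ± 0.819 at day 7, 2.63% ± 1.75 at day 14 and 3.30% ± 0.856 at day 21. At Leiden resolution 2 a small cluster carried neutrophil markers and made up 0.0914% ± 0.0598 of cells in the 9 SNI libraries and 0.451% ± 0.363 in the 2 sham libraries (exact permutation p = 0.0364, the smallest this design can give; adjusted p = 0.6545). On an axis that runs from 0 for the mean of the day 3 and 7 libraries to 1 for the mean of the day 14 and 21 libraries, over genes called between them, sham replicate 1 lay at 0.09, 0.39, -0.10 and -0.05 and sham replicate 2 at 0.15, 0.18, 0.20 and 0.25 in endothelial cells, mature oligodendrocytes, microglia and precursors. Early SNI libraries lay between -0.28 and 0.28 and late ones between 0.92 and 1.13. The axis fixes that separation, since its ends and genes come from these same libraries, so only the sham positions are informative. Deviations of sham replicate 1 from the mean of all libraries, across genes, correlated with those of SNI day 7 replicate 1 at r = 0.49, 0.33, 0.77 and 0.41, and with those of sham replicate 2 at -0.19, -0.27, -0.05 and 0.02.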
